A study of Mus musculus with 18 samples.

How the data were processed

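RNA from whole brain, kidney and liver of DBA/2J and C57BL/6J mice was compared on 18 two-colour glass arrays, 6 per tissue. Per the labels, DBA/2J RNA carried the longer-wavelength and C57BL/6J RNA the shorter-wavelength of a pair of Alexa Fluor dyes on every array, and no dye swaps were made. Per the labels, each pool held RNA of 10 mice for brain and kidney and of 9 for liver, and all arrays of a tissue used common pools. The deposited table holds log2 ratios for 23040 spots on each array. Per the labels, spots were quantified with Spot and the ratios were normalised by print-tip lowess with limma. The versions and the background correction are not given in the sources used here.

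The deposited values did not have the properties of normalised ratios. All of the values of the 21765 spots used (100.0%) were log2 of a ratio of 2 whole numbers, to a tolerance of 1e-12, array medians lay between -1.65 and 0.16, and ratios correlated with intensity by up to 0.715. The values were therefore treated as log2 ratios of raw intensities. This departs from the design fixed before the data were examined, which took the values to be normalised. Values of 0 on every array were found for 1275 spots, 232 of them named Gapdh and the others without a gene symbol, and these were left out. No other value was missing.

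The whole numbers behind each ratio were recovered by continued fractions, up to a largest intensity of 65535. A ratio fixes the 2 intensities only up to a common factor. The factor was estimated for each spot from the other arrays, with an assumed SD of 0.4 on the log2 scale. On data simulated from these estimates the factor was exact for 75.9% of spots in brain, 75.3% in kidney and 75.9% in liver. The intensity fitted from all arrays of the tissue was off there by a root mean square of 0.392, 0.348 and 0.383 on the log2 scale. The simulated intensities already followed the estimates, so this check does not show how well real intensities were recovered. Log2 ratios were then normalised within each array by print-tip loess in limma (span 0.3, 4 iterations, 48 blocks of 480 spots), against the intensity fitted from the arrays of the tissue. The recovered intensities served this step, the percentiles of spot intensity, random lists matched on intensity, and the choice of features left out as dim or saturated.

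Genes were named from the platform annotation, with symbols updated through a RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, which matched 15964 spots. A single symbol was held by 16642 spots, several by 134 and none by 4989. Spots with the same single symbol were averaged, which gave 20218 features and 15095 named genes, 1047 of them with more than 1 spot. Spots of the same gene often disagreed. Among 902 genes with 2 spots the ratios of the spots correlated, across genes, with Pearson's r of 0.0742 in brain, 0.103 in kidney and 0.0302 in liver. For the 178 of these genes whose spots had like intensity profiles over the tissues (correlation above 0.9, range above 1 on the log2 scale) it was 0.0642, 0.344 and 0.194. Gene names are therefore uncertain for part of the spots. The low agreement of spots with like profiles leaves open that a ratio also depends on the spot itself. Where both spots passed the threshold the signs matched for 13 of 16 genes in brain, 66 of 124 in kidney and 31 of 60 in liver.

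For each tissue the mean log2 ratio of the 6 arrays was tested against 0 with limma (lmFit and eBayes), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05 that also applies to every count given as past the threshold. A second count also asked for a 1.5-fold ratio. Differences between tissues were contrasts in a fit of the 18 arrays, whose n is 6 arrays per tissue. Errors are SDs over the 6 arrays, or standard errors (SE) for differences. A further test used 1 averaged value per tissue. Pearson's r describes the ratios across features. Chromosomes were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 20 chromosomes.

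Gene lists of pathways, cell types and known strain alleles were written before the data were examined, 40 lists with 1533 genes, of which 1264 were on the arrays. The 39 lists with at least 5 measured genes were tested with camera in limma, with a preset correlation of 0.01 between genes, and beside it with an estimated correlation and with fry. Named genes followed a rule also set before the data were examined. It took, per tissue, the 10 highest and the 10 lowest mean ratios among genes past the threshold with the same sign on every array, up to 4 members past the threshold of each list described, all known alleles, the 5 largest differences each way per pair of tissues among genes past 1.5-fold in at least 1 of the pair, and the 8 highest and 8 lowest means among genes past the threshold in all 3 tissues in a single direction.

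The steps from normalisation onward were run on simulated data with known ratios over 20218 features. Log2 ratios of 0.3, 0.6 and 1 in size were given to 66, 67 and 67 of them, in kidney alone for the differences. Log2 ratios of 0.3, 0.6 and 1 were recovered for 19.7%, 76.1% and 97.0% of features in brain, 30.3%, 94.0% and 100.0% in kidney and 22.7%, 89.6% and 98.5% in liver, and false calls made up 3.01%, 1.96% and 2.76% of calls. For the brain and kidney difference 10.6%, 74.6% and 98.5% were recovered, and for the kidney and liver difference 9.09%, 79.1% and 100.0%, with false calls at 12.8% and 7.35% of calls. A list moved by 0.3 in brain was called, and 0 other lists were. The simulated trends were those that loess had removed from the real arrays, and they were fitted again against the same intensity. The simulation therefore could not test whether loess or the recovered intensity suits the real data. The shares of false calls need not hold for the real counts. The simulated noise was independent between spots, so the preset correlation was not tested either. In the data the estimated correlation in brain was 0.604 for ribosomal protein genes and 0.243 for oxidative phosphorylation.

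The alternatives tried were median centring without loess, a common scale for all arrays, each spot on its own, a robust prior, array weights, a single fit for all tissues, the replicate number as a block, and leaving out each array in turn. Alternatives added after the data were seen were the values as deposited, loess over the whole array, the intensity of each array itself, the intensity without the restored factor, and leaving out dim or saturated features. The work used R 4.3.3, limma 3.58.1, statmod 1.5.0, python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.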

Results

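RNA levels in whole brain, kidney and liver were compared between 2 inbred mouse strains, DBA/2J and C57BL/6J, on 18 glass oligonucleotide arrays, 6 per tissue. On each array a pool of DBA/2J RNA was hybridised together with a pool of C57BL/6J RNA. The pools were made from 10 mice for brain and kidney and from 9 for liver, and all 6 arrays of a tissue drew on the same pair of pools. The p-values given here therefore measure the spread between hybridisations of the same RNA pools, not the spread between mice. The 6 arrays per tissue limit the precision of each mean. The table held 21765 spots with a value on every array, and the spots were combined into 20218 features, 15095 of them named genes. The names follow the platform annotation and were not tested against spot sequences. The 2 spots of 902 genes agreed poorly (Pearson's r across genes of 0.0742 in brain, 0.103 in kidney and 0.0302 in liver), so the name of part of the spots is uncertain. For 178 of these genes, whose spots had like intensity profiles over the tissues, it was 0.0642, 0.344 and 0.194. A ratio may therefore also depend on the spot itself, and a single spot may not stand for its gene even where the name is right. As deposited, the median log2 ratio of replicates 1 to 6 was -0.22, -0.93, -1.04, -0.61, -1.496 and -1.29 in brain, -0.74, -0.85, -0.48, -0.24, 0.16 and -0.75 in kidney, and -1.65, -1.18, -1.13, -0.89, -0.77 and -1.06 in liver. After normalisation the mean correlation between arrays of a tissue, across spots, was 0.378 in brain, 0.615 in kidney and 0.472 in liver. Positive values stand for higher levels in DBA/2J. This direction is likely rather than stated. It rests on the dyes in the labels and on the usual order of the channels in limma, and the next comparison bears on it.

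The first question was whether genes with long-known allelic differences between the strains differed in the direction that those alleles give. Glo1, which encodes glyoxalase 1 and is duplicated in DBA/2J, was higher in DBA/2J in all 3 tissues, by 0.63 ± 0.13 in brain, 0.84 ± 0.34 in kidney and 0.91 ± 0.14 in liver (log2 ratio, mean ± SD, n = 6 arrays), or 1.55-fold, 1.79-fold and 1.87-fold. H2-Ea, a class II antigen gene that C57BL/6J does not express, was higher in kidney (0.84 ± 0.34) and liver (0.63 ± 0.34), and stood at 0.22 ± 0.18 in brain without passing the threshold (adjusted p = 0.0890). Nnt, the mitochondrial transhydrogenase gene that carries a deletion in C57BL/6J, was higher in liver (0.58 ± 0.27) and in kidney (0.49 ± 0.54, adjusted p = 0.0183), but not in brain (0.05 ± 0.48). Brain array 1 stood far below the others for Nnt, at -0.88. Hc, which encodes complement C5 and is defective in DBA/2J, was lower in DBA/2J liver, the organ that makes most C5, by 2.14-fold (-1.10 ± 0.52), and in kidney (-0.25 ± 0.07). Gabra2, a GABA-A receptor subunit gene with reduced expression in C57BL/6J, was higher in DBA/2J brain (0.45 ± 0.15).

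Gabra2 went the other way in kidney (-0.23 ± 0.23, adjusted p = 0.0421), where its 2 spots gave 0.06 and -0.51. Without kidney array 4, 5 or 6 that call ended, with -0.21, -0.15 and -0.22. Gpnmb, which carries a stop codon in DBA/2J, was lower in kidney (-0.35 ± 0.22) and in liver (-0.23 ± 0.16, adjusted p = 0.0402). The kidney value became 0.19 without loess, and the liver call ended without any 1 of liver arrays 1, 2, 3, 4 and 6, with values from -0.25 to -0.19. Klrd1, deleted in DBA/2J, was lower in kidney (-0.32 ± 0.13), and Alad, duplicated in DBA/2J, passed in no tissue (0.12, 0.04 and 0.08). The kidney call of Nnt ended without kidney array 2, 4, 5 or 6, with means of 0.46, 0.41, 0.44 and 0.41. In all, 13 of the 24 gene and tissue combinations passed in the direction of the known allele. The genes with higher known expression in DBA/2J had a median of 0.22 in brain (2 higher and 0 lower of 5, or 3 past the threshold adjusted over the list alone), 0.49 in kidney (3 higher and 1 lower, 4 over the list alone) and 0.58 in liver (3 higher and 0 lower, 3 over the list alone). The set test against all other genes gave adjusted p = 0.0171, 0.179 and 0.00687, and adjusted p = 0.547, 0.545 and 0.580 with an estimated correlation. The 3 genes with lower known expression were too few for a set test. They passed as lower in 0 tests in brain, 3 in kidney and 2 in liver, with the same counts adjusted over the list alone.

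**Figure D1:**
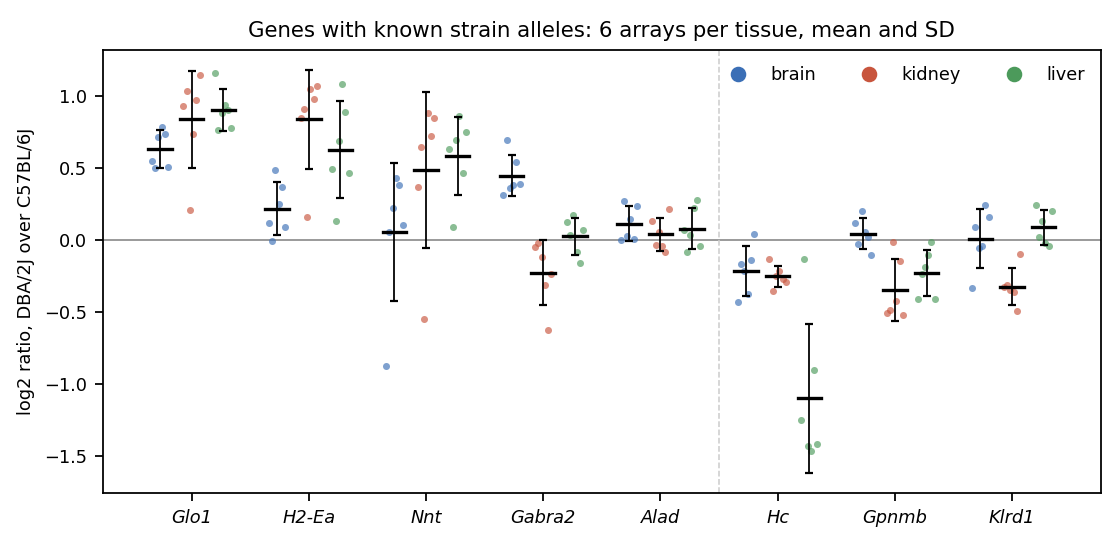
Log2 ratio of DBA/2J over C57BL/6J (vertical axis) for 8 genes with known strain alleles in brain, kidney and liver, with a point for each of the 6 arrays and a line at the mean with its SD. Glo1 lies above 0 on every array, with means of 0.63, 0.84 and 0.91, Hc in liver lies at -1.10, and Gpnmb in kidney, at -0.35, turns to 0.19 without loess.

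The strain comparison in whole brain asked which genes differed in RNA level between DBA/2J and C57BL/6J brain. Pam, which encodes the enzyme that amidates neuropeptides, was 4.76-fold higher in DBA/2J (2.25 ± 0.59, mean log2 ratio ± SD, n = 6 arrays, adjusted p = 1.61e-05). Bid, which encodes a pro-apoptotic protein of the BCL-2 family, was 6.57-fold lower (-2.72 ± 0.54), and the homeobox gene Hmx2 was 4.83-fold lower (-2.27 ± 0.75). Among the other genes higher in DBA/2J were Thbs2, a matricellular thrombospondin (3.01-fold, 1.59 ± 0.51), Neurl3, a ubiquitin ligase (2.97-fold, 1.57 ± 0.21), and Vip, the neuropeptide vasoactive intestinal peptide (2.02-fold, 1.01 ± 0.62, adjusted p = 0.00408). The transcripts E130101E03Rik (1.29 ± 0.48) and 1700001L05Rik (1.02 ± 0.42) and the cytochrome P450 gene Cyp2a5 (1.01 ± 0.67) were higher as well. The olfactory receptor gene Olfr76 reached 1.62 ± 0.30 at percentile 7.38 of spot intensity, and Il9r (1.11 ± 0.56) and Slc9a9 (1.01 ± 0.39) lay among the dimmest spots, at percentile 0.119.

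On the lower side in brain, Mmp9, a matrix metalloproteinase, stood at -1.58 ± 0.21 (2.99-fold), Sh3bp1 at -1.56 ± 0.27 (2.94-fold) and the ubiquitin ligase Hectd3 at -1.41 ± 0.18 (2.67-fold). The ferritin light chain gene Ftl1 was 2.51-fold lower (-1.33 ± 0.67), the ATP-gated channel gene P2rx5 2.44-fold lower (-1.29 ± 0.46) and Hydin, a gene of motile cilia, 2.21-fold lower (-1.14 ± 0.63). Apoc1, an apolipoprotein gene, averaged -1.63 ± 1.26 (adjusted p = 0.00900), with array 1 at -4.10 and the other arrays between -1.61 and -0.80. Tfam, the mitochondrial transcription factor, averaged -1.32 ± 1.52 (adjusted p = 0.0459), with array 4 at -4.36 and the others between -1.15 and -0.40, and its call ended without array 1, 3, 5 or 6, with means of -1.35, -1.38, -1.4996 and -1.48, and with the intensity left unrestored (-1.10). Without array 4 the mean was -0.71, still past the threshold. In total 2710 of 20218 features passed the threshold, 1477 higher and 1233 lower in DBA/2J, a split that turned to 1660 higher and 1885 lower without loess. Of these, 343 differed at least 1.5-fold (211 higher, 132 lower), against 823 without loess, and 35 at least 2-fold. All 6 arrays had the same sign for 17.7% of features, against 3.12% by chance. The number past the threshold fell to 1571, 1244, 1348 and 1379 without brain array 2, 4, 5 or 6.

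Of 39 gene lists fixed before the data were examined, 6 passed the set test in brain. Cytosolic ribosomal protein genes stood highest, with 30 of 62 measured genes higher, 0 lower and 32 not past the threshold (38 past it adjusted over the list alone, median 0.36, adjusted p = 9.89e-15, and adjusted p = 0.589 with an estimated correlation). Fau (0.85 ± 0.44), Rps25 (0.75 ± 0.38), Rpl38 (0.74 ± 0.52) and Rps29 (0.69 ± 0.34) had the largest ratios. Genes of oxidative phosphorylation followed with 21 higher, 2 lower and 49 not past of 72 (31 over the list alone, median 0.18, adjusted p = 1.55e-05, and adjusted p = 0.606 with an estimated correlation), among them Ndufb3 (0.56 ± 0.36), Atp5j2 (0.56 ± 0.31) and Cox5a (0.55 ± 0.34), while the complex I gene Ndufa13 was lower (-0.62 ± 0.23, not past the threshold without loess). Both groups were also higher under every other scaling of the arrays that was tried. On brain array 1 alone the medians of the 2 lists lay below 0, at -0.10 and -0.07. With any 1 brain array left out they stayed at 0.28 and 0.14 or more.

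Lists of astrocyte and of myelin genes passed the set test in brain on the lower side, although most of their genes did not pass the threshold. Of 22 astrocyte genes 2 were higher, 7 lower and 13 not past the threshold (10 past it over the list alone, median -0.09, adjusted p = 0.0381, and adjusted p = 0.547 with an estimated correlation). Glul, the glutamine synthetase gene, was 1.92-fold lower (-0.94 ± 0.33) and S100b 1.40-fold lower (-0.48 ± 0.41, but -0.32 without brain array 6, and not past the threshold without loess), whereas Apoe was 1.29-fold higher (0.37 ± 0.19). Of 23 genes of myelin and oligodendrocytes 0 were higher, 4 lower and 19 not past (5 over the list alone, median -0.09, adjusted p = 0.0314, and adjusted p = 0.547 with an estimated correlation), with the myelin proteolipid Mal at -0.51 ± 0.10 and the connexin gene Gjb1 at -0.40 ± 0.19, the latter not past the threshold without loess. Genes of microglia and macrophages did not pass as a list, with 0 higher, 4 lower and 28 not past of 32 (3 over the list alone, adjusted p = 0.512). A list of transporters of the proximal tubule of the kidney gave 1 higher, 5 lower and 44 not past of 50 in brain (4 over the list alone, median -0.10, adjusted p = 0.0381, and adjusted p = 0.547 with an estimated correlation). Its largest member was Slc34a1, a phosphate transporter, at -0.50 ± 0.33. The medians of the astrocyte, myelin and proximal tubule lists stayed below 0 under every scaling tried, but none of these 3 passed with the intensity left unrestored, where 3 brain lists passed, the ribosomal, oxidative phosphorylation and known higher alleles lists. The 6 brain lists were 3 on the higher and 3 on the lower side, against 4 and 2 without loess, 3 and 0 with the intensity left unrestored and 3 and 1 without brain array 1, 3 or 5.

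In kidney the same question gave the largest number of differences. Ttll8, a tubulin glycine ligase, was 5.83-fold higher in DBA/2J (2.54 ± 0.41, mean log2 ratio ± SD, n = 6 arrays, adjusted p = 9.10e-09) and Satl1, a gene related to spermidine acetyltransferase, 4.41-fold higher (2.14 ± 0.37). Among the 10 highest were the retinaldehyde dehydrogenase Aldh1a1 (3.84-fold, 1.94 ± 0.45), the fatty acid hydroxylase Cyp4a12a (3.67-fold, 1.88 ± 0.73), the related Cyp2a4 (3.09-fold, 1.63 ± 0.63) and Cyp2a5 (2.86-fold, 1.52 ± 0.76), and the peroxisomal oxidase Hao2 (2.83-fold, 1.501 ± 0.43). On array 3 each of the last 4 was lower than on the other arrays, at 0.41, 0.37, 0.02 and 0.66. The list of enzymes of drug and xenobiotic metabolism as a whole gave 10 higher, 15 lower and 34 not past the threshold of 59 in kidney (25 past it over the list alone, median -0.01, but 0.01 without loess, adjusted p = 0.853). Pam was 3.16-fold higher (1.66 ± 0.29) and the centrosomal gene Cep20 3.15-fold higher (1.65 ± 0.84). The transcript 5031434O11Rik averaged 1.83 ± 1.73 (adjusted p = 0.00494), with arrays 5 and 6 at 4.79 and 3.09 and the others between 0.48 and 0.99.

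Among named genes past the threshold with the same sign on every array, the lowest ratios in kidney belonged to Bid (7.08-fold lower, -2.82 ± 0.59), to the ferritin light chain gene Ftl1 (5.01-fold, -2.33 ± 0.59) with its pseudogene Ftl2-ps (4.53-fold, -2.18 ± 0.35), and to Dpp6, an auxiliary subunit of potassium channels (4.94-fold, -2.30 ± 0.33). Mmp9 was 4.33-fold lower (-2.12 ± 0.23), Rhbdf1, an inactive rhomboid protease, 4.13-fold lower (-2.05 ± 0.41) and Ogfrl1 3.60-fold lower (-1.85 ± 0.33). Of the glandular kallikrein genes 3 were among the 10 lowest and lower on every kidney array, with Klk1b24 at -2.02 ± 0.13, Klk1b19-ps at -1.87 ± 0.18 and Klk1b11 at -1.80 ± 0.13, where the 3 spots of Klk1b11 gave -1.84, -1.81 and -1.76. Members of the Klk1b, Ftl and Cyp2a families are close in sequence, and which member a spot measured is uncertain. Past the threshold were 7682 of 20218 features, 3862 higher and 3820 lower. Of these, 784 differed at least 1.5-fold (325 higher, 459 lower) and 124 at least 2-fold. The median SD between arrays was 0.178 in kidney, 0.197 in brain and 0.183 in liver, so the numbers called per tissue do not rest on equal precision. Where both spots of a gene passed in kidney, the signs matched for 66 of 124 genes. All 6 arrays had the same sign for 33.5% of features. Kidney ratios depended more than the others on spot intensity before normalisation (correlation up to 0.715 on 1 array), and without loess 13113 features passed, 6468 higher and 6645 lower, 5748 of them at 1.5-fold. With the intensity left unrestored 6772 passed, 3201 higher and 3571 lower, and 1364 did so at 1.5-fold.

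In kidney 3 of the 39 lists passed the set test, each of them on the lower side, against 9 higher and 2 lower without loess and 1 higher and 3 lower with the intensity left unrestored. Without the dimmer part of the features 1 kidney list passed, on the lower side. Leaving out each kidney array in turn gave 2 to 3 lists. Of 28 genes of GABA and glycine signalling 2 were higher, 12 lower and 14 not past the threshold (16 past it over the list alone, median -0.16, adjusted p = 0.0111, and adjusted p = 0.450 with an estimated correlation). The receptor subunit genes Gabra5 (-0.81 ± 0.22), Gabra3 (-0.78 ± 0.28) and Glra1 (-0.67 ± 0.14) and the glycine transporter gene Slc6a9 (-0.75 ± 0.27) had the largest ratios, and the spots of Gabra5 lay at percentile 7.20 of intensity. The list median was also below 0 in brain (-0.09) and liver (-0.08), where the set test did not pass (adjusted p = 0.101 and 0.229). Gabra5 (-0.43 and -0.51) and Slc6a9 (-0.60 and -0.49) were lower past the threshold in brain and liver too. A dye effect constant for a spot is not separated from strain here. Of 39 genes of the distal tubule and collecting duct 4 were higher, 18 lower and 17 not past (22 over the list alone, median -0.15, adjusted p = 0.0111, and adjusted p = 0.545 with an estimated correlation), and without loess the median turned to 0.15. The potassium channel gene Kcnj1 was lower (-0.80 ± 0.23), as were uromodulin, Umod (-0.74 ± 0.10, but 0.11 without loess), and the sodium channel subunit gene Scnn1a (-0.57 ± 0.18, but 0.15 without loess), while the water channel gene Aqp4 was higher (0.63 ± 0.46). Ribosomal protein genes, with 4 higher, 22 lower and 36 not past of 62 (26 over the list alone, median -0.10, adjusted p = 0.0309, and adjusted p = 0.736 with an estimated correlation), had a median of 0.66 without loess and 0.01 with the intensity left unrestored. Rpl27a (-0.44 ± 0.08), Rpl9 (-0.44 ± 0.21) and Rps6 (-0.43 ± 0.10) turned to 0.39, 0.61 and 0.53 without loess, and Rpl14 was higher (0.42 ± 0.23). The genes of the adrenal gland, an organ next to the kidney, gave 2 higher, 4 lower and 7 not past of 13 (6 over the list alone, adjusted p = 0.684).

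In liver, Fgf2, a fibroblast growth factor, was 5.45-fold higher in DBA/2J (2.45 ± 1.09, mean log2 ratio ± SD, n = 6 arrays, adjusted p = 0.000206), with array 2 at 0.55. Mt1, a metallothionein that binds zinc and copper, was 3.77-fold higher (1.91 ± 0.27) and Apcs, the plasma protein serum amyloid P, 3.44-fold higher (1.78 ± 0.31). The actin gene Acta1 (2.92-fold, 1.54 ± 0.74), Satl1 (2.74-fold, 1.45 ± 0.69), the kinase gene Stk32c (2.68-fold, 1.42 ± 0.69), the small RNA gene Rny1 (2.43-fold, 1.28 ± 0.24) and Msmo1, an enzyme of cholesterol synthesis (2.42-fold, 1.28 ± 0.46), were also higher. The spots of Actl7a (1.29 ± 0.19) and Rian (1.23 ± 0.49) were among the dimmest, at percentiles 0.482 and 0.739. Skeletal muscle markers, to which Acta1 belongs, gave 4 higher, 2 lower and 12 not past of 18 (8 over the list alone, adjusted p = 0.545).

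Ftl1 was 4.29-fold lower in liver (-2.10 ± 1.28) and Ftl2-ps 2.73-fold lower (-1.45 ± 0.54). The formyl peptide receptor gene Fpr2 was 4.12-fold lower (-2.04 ± 1.03), Bid 3.22-fold lower (-1.69 ± 0.72), the aldehyde oxidase Aox3 2.85-fold lower (-1.51 ± 0.34) and Mmp9 2.47-fold lower (-1.30 ± 0.30). The transcripts Bcas3os2 (-1.77 ± 0.84) and C730007P19Rik (-1.36 ± 0.45) were lower too, and Tmco5 (-1.79 ± 0.42) lay at intensity percentile 0.153. Amy2, the amylase gene of the pancreas, was 3.21-fold lower (-1.68 ± 0.51), and genes of pancreas and gut as a list gave 3 higher, 7 lower and 12 not past of 22 (10 over the list alone, adjusted p = 0.0963, and adjusted p = 0.609 with an estimated correlation). In total 4619 of 20218 features passed the threshold, 2176 higher and 2443 lower. Of these, 477 differed at least 1.5-fold, 150 higher and 327 lower, and 89 at least 2-fold. The split at 1.5-fold was 313 higher and 363 lower without loess, and 231 higher and 291 lower with the intensity left unrestored. All 6 arrays had the same sign for 24.7% of features. The number past the threshold was 2895 without liver array 3.

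Of the 39 lists 5 passed in liver, 3 higher and 2 lower, against 4 and 1 without loess and 3 and 1 with whole-array loess and with the intensity left unrestored. Chaperone and stress genes were lower, with 4 higher, 18 lower and 13 not past of 35 (23 over the list alone, median -0.32, adjusted p = 4.38e-05, and adjusted p = 0.108 with an estimated correlation). The small heat shock protein genes Cryab (-0.996 ± 0.24) and Hspb1 (-0.69 ± 0.38) and the endoplasmic reticulum stress genes Herpud1 (-0.82 ± 0.15) and Dnajb9 (-0.81 ± 0.45) led the list. Genes of the major histocompatibility complex and antigen presentation were also lower, with 2 higher, 12 lower and 21 not past of 35 (16 over the list alone, median -0.13, adjusted p = 0.0274, and adjusted p = 0.580 with an estimated correlation). The class I genes H2-M2 (-0.77 ± 0.40), H2-Q7 (-0.74 ± 0.11), H2-Q10 (-0.64 ± 0.20) and H2-K1 (-0.63 ± 0.31) were lower. The strains carry different alleles of these genes, and H2-Ea of class II was higher, as given for the known alleles. Ribosomal protein genes gave 26 higher, 3 lower and 33 not past of 62 (35 over the list alone, median 0.17, adjusted p = 1.17e-05, and adjusted p = 0.609 with an estimated correlation), led by Rplp1 (0.71 ± 0.31), Rps15 (0.65 ± 0.31), Rps25 (0.53 ± 0.28) and Rps28 (0.50 ± 0.27). Oxidative phosphorylation gave 23 higher, 4 lower and 45 not past of 72 (32 over the list alone, median 0.13, adjusted p = 0.000879, and adjusted p = 0.603 with an estimated correlation), with Uqcr10 at 0.44 ± 0.19, Atp5e at 0.43 ± 0.17 and Cox5a at 0.39 ± 0.15. The direction of each of these medians was the same under every scaling tried. The chaperone list also leaned lower in kidney (4 higher, 13 lower, set test adjusted p = 0.152) but not in brain (3 and 3). Cryab (-0.50 and -1.19) and H2-M2 (-0.35 and -0.63) were lower past the threshold in brain and kidney too. The other chaperone and antigen presentation genes named here did not pass as lower in all 3 tissues. For Cryab and H2-M2 a dye effect constant for a spot is not separated from strain. In no tissue did a list pass with an estimated correlation between genes (0 of 39 in brain, kidney and liver), where limma's camera gave 3, 1 and 3 lists at an unadjusted p below 0.05. The rotation test fry, which tests whether the genes of a list move on balance in a single direction and does not compare them with other genes, gave 12 lists in brain, 18 in kidney and 14 in liver. Ribosomal protein genes and oxidative phosphorylation did not pass fry in brain (adjusted p = 0.0720 and 0.0926). In liver both passed it (adjusted p = 0.0485 and 0.0429), and in kidney ribosomal protein genes did not (adjusted p = 0.0509).

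**Figure D2:**
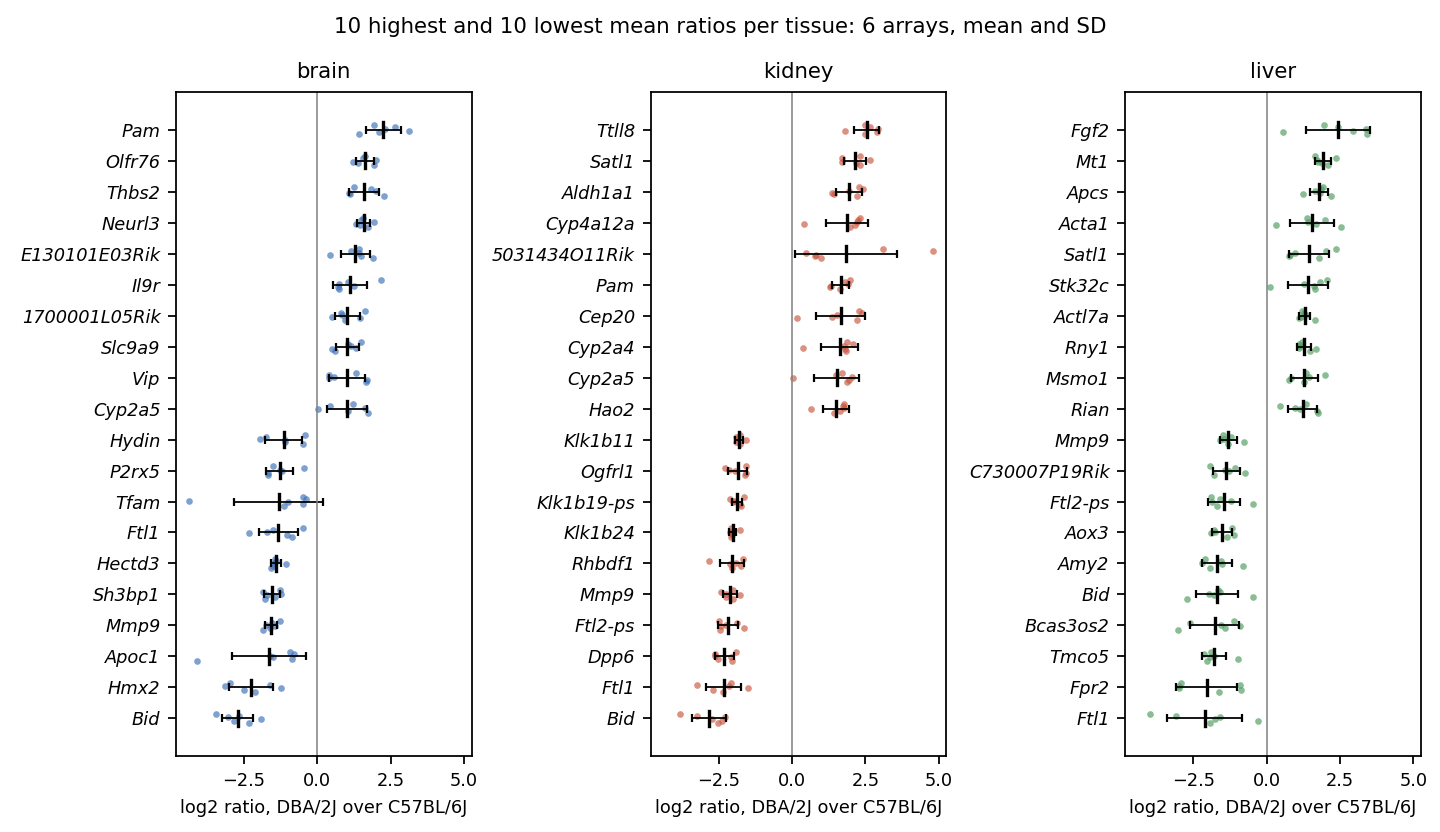
Log2 ratio of DBA/2J over C57BL/6J (horizontal axis) for the 10 highest and 10 lowest named genes of brain, kidney and liver, with a point for each of the 6 arrays and a bar for the mean with its SD. Pam leads in brain with 2.25, Ttll8 in kidney with 2.54 and Fgf2 in liver with 2.45, and Bid stands lowest in brain and kidney with -2.72 and -2.82.

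The third question was which strain differences were shared by the tissues. Bid was lower in DBA/2J in brain, kidney and liver (-2.72, -2.82 and -1.69), as were Ftl1 (-1.33, -2.33 and -2.10), Mmp9 (-1.58, -2.12 and -1.30), Ftl2-ps (-0.75, -2.18 and -1.45) and Rhbdf1 (-0.91, -2.05 and -1.03). Hydin stood at -1.14, -1.34 and -0.98, and Dpp6 at -0.33, -2.30 and -1.09, where the brain call ended without brain array 1, 2, 3 or 6 (-0.29, -0.31, -0.28 and -0.36). Wtap, a component of the RNA methyltransferase complex, averaged -1.04, -1.64 and -1.03 over 2 spots that disagreed, 1 at -0.12, -0.03 and -0.24 and the other at -1.95, -3.25 and -1.83. Higher in DBA/2J in the 3 tissues were Pam (2.25, 1.66 and 0.59), Satl1 (0.97, 2.14 and 1.45), Cyp2a5 (1.01, 1.52 and 0.69), the transcript 9530029F08Rik (0.99, 1.38 and 0.57) and the homeobox gene Meis1 (0.96, 1.46 and 0.40). The liver call of Meis1 (adjusted p = 0.0451) ended without liver array 1, 2, 3 or 6, with 0.36, 0.40, 0.46 and 0.24. Hspa14 (0.76, 1.10 and 1.18), Zfp354a (0.90, 1.02 and 0.79) and Actl7a (0.72, 0.55 and 1.29) completed the 8 highest. Without loess their kidney means were 0.19, 0.19 and 0.24 and did not pass, and Hspa14 and Zfp354a lay at or below intensity percentile 1.75 in every tissue.

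Past the threshold in all 3 tissues in a single direction were 569 features, 176 higher and 393 lower, where independent lists of these sizes would share 30.4 and 28.1. Without loess there were 1512, split into 668 higher and 844 lower. The number fell to 328 and 363 without brain array 4 or 5. A further 107 features passed in all 3 tissues with mixed directions, 2755 passed in exactly 2 tissues and 7473 in exactly 1. Brain and liver shared 596 higher features (159 expected of independent lists) and 517 lower ones (149 expected), and 75 went in opposite directions (311 expected). Kidney and liver shared 695 higher (416 expected) and 1209 lower (462 expected), with 436 opposite (878 expected), and brain and kidney shared 396 (282 expected) and 633 (233 expected), with 226 opposite (515 expected). Across features, which are not independent replicates, the mean ratios of brain and liver correlated with Pearson's r of 0.445, those of kidney and liver with 0.370 and those of brain and kidney with 0.311. The value for brain and kidney was 0.610 without loess and 0.179 without the dimmer part of the features, which also lowered that for kidney and liver to 0.240. No dye swaps were made, so a dye effect that is constant for a spot is not separated from strain in these counts. With each tissue counted as 1 value, 0 features passed in limma (n = 3, lowest adjusted p = 0.0534), and 3736 had an unadjusted p below 0.05. That count rose from 0 to between 5 and 41 when any 1 of 9 arrays was left out, brain 2 (13) and 5 (19), kidney 5 (26) and liver 1 to 6 (41, 5, 21, 33, 23 and 13). It was 506 with whole-array loess, 45 with the intensity of each array itself, 32 with a common scale, 18 without saturated features, 12 with each spot on its own and 5 with the intensity left unrestored.

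**Figure D3:**
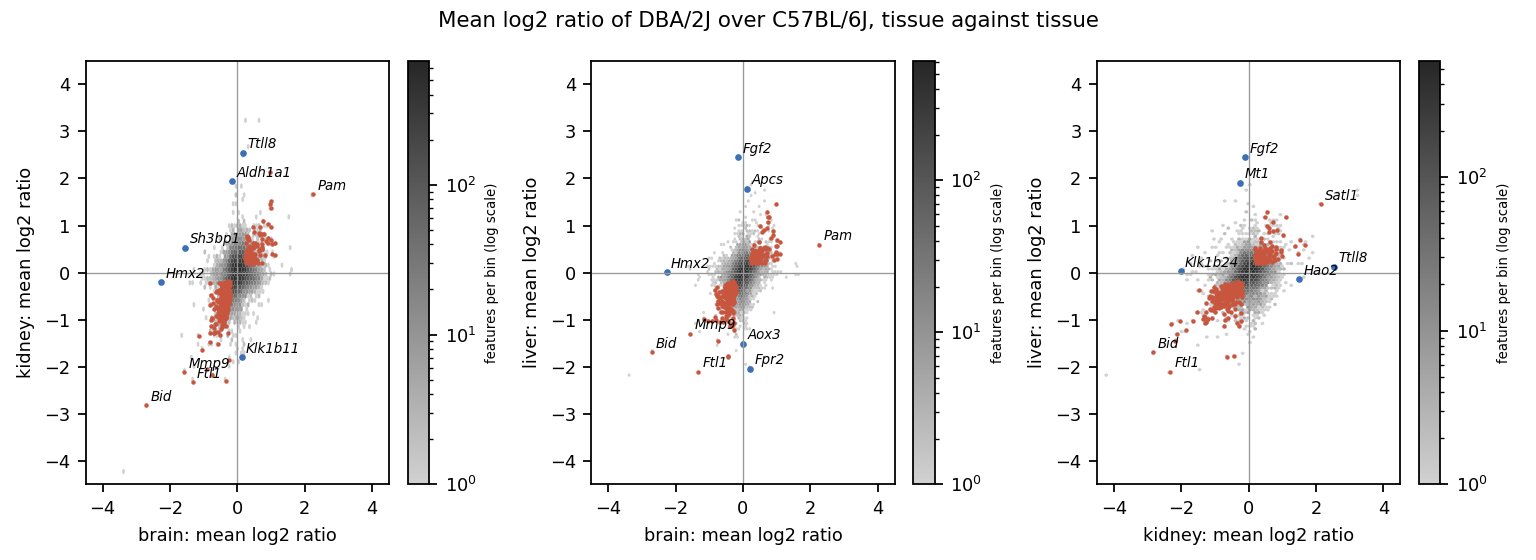
Mean log2 ratio of DBA/2J over C57BL/6J of each of 20218 features in 1 tissue against another, in 3 panels, with darker grey for more features. Features with a gene symbol past the threshold in all 3 tissues in a single direction are in red, such as Bid at -2.72 in brain and -2.82 in kidney, and labelled genes past it in fewer tissues are in blue, such as Ttll8 at 2.54 in kidney and 0.16 in brain.

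The last question was where the strain ratio itself depended on the tissue, tested in a joint fit of the 18 arrays in which a constant dye effect of a spot cancels. Ttll8 was higher in DBA/2J kidney by 2.54 but stood at 0.16 in brain and 0.13 in liver (brain minus kidney -2.38 ± 0.16 SE, adjusted p = 2.32e-10, and kidney minus liver 2.42 ± 0.16 SE, adjusted p = 1.95e-10). Of the glandular kallikreins, Klk1b11 stood at 0.12 in brain and -1.80 in kidney (1.92 ± 0.09, adjusted p = 1.14e-12), Klk1b2-ps at 0.39, itself past the threshold (adjusted p = 0.0368), and -1.44 (1.82 ± 0.14), and Klk1b24 at -2.02 in kidney and 0.02 in liver (-2.04 ± 0.13). Genes of alpha-1-antitrypsin were lower in DBA/2J kidney relative to brain, by 1.88 ± 0.25 for Serpina1b and 1.84 ± 0.19 for Serpina1a, and relative to liver, by -2.07 ± 0.22 for Serpina1e and -2.03 ± 0.25 for Serpina1b. Aldh1a1 stood at -0.15 in brain and 1.94 in kidney (-2.09 ± 0.17). Sh3bp1 was lower in brain (-1.56), higher in kidney (0.53) and at 0.07 in liver (brain minus kidney -2.08 ± 0.13, brain minus liver -1.62 ± 0.13). Hmx2 was lower in brain (-2.27), with -0.21 in kidney and 0.01 in liver (-2.06 ± 0.22 and -2.28 ± 0.22), and Dpp6 was lower in kidney than in brain by 1.97 ± 0.16.

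Liver stood apart from brain in Fgf2 (-0.15 in brain, 2.45 in liver, difference -2.59 ± 0.31), Fpr2 (0.20 and -2.04, 2.24 ± 0.31), Aox3 (0.01 and -1.51, 1.52 ± 0.15) and Apcs (0.12 and 1.78, -1.66 ± 0.15). For Apoc1 it was brain that lay far from 0 (-1.63 in brain, 0.13 in liver, -1.76 ± 0.37, adjusted p = 0.00316). Pam (1.66 ± 0.20), Olfr76 (1.68 ± 0.14) and Thbs2 (1.60 ± 0.17) differed because their brain ratios were the larger ones. Liver stood apart from kidney in Fgf2 (-2.55 ± 0.31) and in Mt1, at -0.24 in kidney and 1.91 in liver (-2.16 ± 0.14). Kidney had the larger ratio for Cep20 (1.65 in kidney, -0.13 in liver, 1.78 ± 0.23) and Hao2 (1.501 and -0.14, 1.64 ± 0.15). The same held for Acsm1, an acyl-CoA synthetase at 1.30 in kidney and -0.25 in liver (1.55 ± 0.13). The transcript 5031434O11Rik differed between brain and kidney (-1.84 ± 0.46, adjusted p = 0.00668) and between kidney and liver (1.53 ± 0.46, adjusted p = 0.0247). The latter call ended without kidney array 6 (1.27, adjusted p = 0.0682) or liver array 1 (1.47, adjusted p = 0.0506), and without kidney array 5 the difference was 0.93. Several of the smaller ratios came from dim spots. Intensity percentiles were 14.7 in brain and 22.1 in kidney for Fgf2, and 19.6 in kidney and 16.7 in liver for Hmx2. They were 2.40 in liver for Pam and 20.8 in brain for Apcs. Other spots were bright there, such as Ttll8 (74.8 in brain, 78.2 in liver), Aldh1a1 (87.6 in brain) and Mt1 (97.2 in kidney). Whether low signal made a ratio small was not tested. In total 4193 features differed between brain and kidney (2201 with the higher ratio in brain, 1992 with the lower), 1465 between brain and liver (819 and 646) and 3266 between kidney and liver (1864 and 1402). Of these, 917, 485 and 904 differed at least 1.5-fold. On simulated data false calls made up 12.8% of the calls between brain and kidney and 7.35% of those between kidney and liver, above the 5% aimed at. These shares came from 18 and 10 false calls in 1 simulation, which changed 66, 67 and 67 features by 0.3, 0.6 and 1. They need not hold for the real counts. The F test over the 3 tissues gave 5253. Without loess the counts were 7113 (3551 and 3562), 830 (472 and 358), 9288 (4418 and 4870) and 9421, so that the larger side turned for both differences that involve kidney. It also turned for brain and kidney with the intensity left unrestored (3092, 1528 and 1564), where brain and liver gave 773, against 868 with whole-array loess. Without the dimmer part of the features, where fewer were tested, brain and kidney gave 2761.

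Of the lists, chaperone and stress genes held lower ratios in liver than in brain, with a median difference of 0.29 over 35 genes (adjusted p = 1.30e-05). This was the only difference between tissues in a list that also passed with an estimated correlation (adjusted p = 0.0280). Ribosomal protein genes had higher ratios in brain than in kidney (median difference 0.46, adjusted p = 8.22e-14), in brain than in liver (0.12, adjusted p = 0.00649) and in liver than in kidney (-0.25 for kidney minus liver, adjusted p = 3.93e-09), with adjusted p = 0.695, 0.718 and 0.390 with an estimated correlation. The array medians of the list did not pass between brain and liver (0.16, exact permutation p = 0.186). Without loess the ribosomal differences from kidney turned, to -0.10 for brain minus kidney and 0.35 for kidney minus liver. For oxidative phosphorylation the ratios in kidney were below those in brain (0.25, adjusted p = 4.44e-05) and in liver (-0.17, adjusted p = 8.79e-05), with adjusted p = 0.695 and 0.390 with an estimated correlation, and without loess both turned, to -0.27 and 0.42. With the intensity left unrestored these 2 differences shrank to 0.11 and -0.02. Astrocyte genes (-0.17, but 0.02 without loess, adjusted p = 0.0329) and circadian clock genes (-0.19, adjusted p = 0.0459) had lower ratios in brain than in kidney, both with adjusted p = 0.387 with an estimated correlation. Between brain and liver, genes of antigen presentation (0.14, adjusted p = 0.0157) and of the proteasome (0.13, adjusted p = 0.00649) had higher ratios in brain, with adjusted p = 0.257 and 0.297 with an estimated correlation. Markers of muscle (-0.10, adjusted p = 0.0178), of myelin (-0.08, adjusted p = 0.0157) and proteins secreted by the liver (-0.11, adjusted p = 0.0178) had lower ones, with adjusted p = 0.257, 0.287 and 0.471 with an estimated correlation. Muscle markers also had lower ratios in kidney than in liver (-0.15, adjusted p = 0.00310, and adjusted p = 0.390 with an estimated correlation).

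The share of named genes past the threshold was compared between chromosomes 1 to 19 and X. These held 14603 of the 14620 genes with a known chromosome. In each tissue 0 of 20 chromosomes passed Fisher's exact test of called against other genes, either at the threshold or at 1.5-fold as well, with 1, 1 and 0 chromosomes at an unadjusted p below 0.05 for brain, kidney and liver at the threshold and 0, 1 and 2 at 1.5-fold. The lowest adjusted p was 0.118, for chromosome 7 in kidney at 1.5-fold, with 5.37% of its genes against 3.67% elsewhere (unadjusted p = 0.00588). In liver at 1.5-fold chromosome 1 had 3.85% against 2.30% elsewhere (unadjusted p = 0.00751, adjusted p = 0.1503) and chromosome 16 had 0.818% against 2.44% (unadjusted p = 0.0152, adjusted p = 0.152).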

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

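The tests of a single array, of loess and of the dye for ribosomal protein genes were chosen after the results were seen, the first of them after an earlier form, which asked for all 6 brain arrays to lie above 0, had been found to hold on 5, and the other 2 after earlier forms without matching on intensity.

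Single arrays stood far from the other 5 in 23 of 196 groups of 6 values (11.7%), by a test that singles out about 5% by chance. In kidney, array 3 stood closest to 0 or lowest in 8 of them. Its log2 ratios were 0.41 for Cyp4a12a, 0.37 for Cyp2a4, 0.022 for Cyp2a5, 0.66 for Hao2, -0.55 for Nnt, 0.16 for H2-Ea, -1.08 for Serpina1a and -0.44 for Serpina1d. In brain, array 1 stood lowest for Apoc1 (-4.10), Slc7a10 (-0.25), Rps25 (0.023) and Nnt (-0.88), array 3 highest for Hectd3 (-1.07), array 4 lowest for Tfam (-4.36), and array 6 highest for Glul (-0.30) and lowest for S100b (-1.30). Klk1b24 was highest on kidney array 5 (-1.76). In liver, array 1 was highest for Dbp (1.86) and Atp5e (0.76), array 2 highest for Tmco5 (-0.96) and lowest for G6pc (-1.31), array 4 highest for Herpud1 (-0.54) and array 5 highest for Cyp2a5 (1.11). Slc7a10, an astrocyte gene, averaged 0.40 in brain and lost its call without brain array 2, 3, 4, 5 or 6 (0.38, 0.41, 0.37, 0.37 and 0.35).

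The strain ratio differed between tissues by the test of the difference itself for 4193 features between brain and kidney, 1465 between brain and liver, 3266 between kidney and liver and 5253 over the 3 tissues. Among named genes past 1.5-fold in at least 1 tissue of a pair, the largest differences of brain minus kidney were 1.97 for Dpp6, 1.92 for Klk1b11, 1.88 for Serpina1b, 1.84 for Serpina1a, 1.82 for Klk1b2-ps, -2.38 for Ttll8, -2.09 for Aldh1a1, -2.08 for Sh3bp1, -2.06 for Hmx2 and -1.84 for 5031434O11Rik. Those of brain minus liver were 2.24 for Fpr2, 1.68 for Olfr76, 1.66 for Pam, 1.60 for Thbs2, 1.52 for Aox3, -2.59 for Fgf2, -2.28 for Hmx2, -1.76 for Apoc1, -1.66 for Apcs and -1.62 for Sh3bp1. Those of kidney minus liver were 2.42 for Ttll8, 1.78 for Cep20, 1.64 for Hao2, 1.55 for Acsm1, 1.53 for 5031434O11Rik, -2.55 for Fgf2, -2.16 for Mt1, -2.07 for Serpina1e, -2.04 for Klk1b24 and -2.03 for Serpina1b. The call of 5031434O11Rik for kidney minus liver ended without kidney array 6 (1.27) or liver array 1 (1.47).

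Among the lists the median differences of brain minus kidney were -0.17 for astrocyte genes, -0.19 for clock genes, 0.25 for oxidative phosphorylation and 0.46 for ribosomal proteins. Those of brain minus liver were 0.29 for chaperones, 0.14 for antigen presentation, -0.10 for muscle, -0.082 for myelin, 0.13 for the proteasome, 0.12 for ribosomal proteins and -0.11 for secreted liver proteins, and those of kidney minus liver were -0.15 for muscle, -0.17 for oxidative phosphorylation and -0.25 for ribosomal proteins. Without loess the values for astrocyte genes, oxidative phosphorylation and ribosomal proteins that involve kidney had the other sign (0.02, -0.27 and -0.10 against brain, and 0.42 and 0.35 against liver).

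Chance among the hybridisations is argued against for the counts of each tissue and each difference. Chance differences between the mice in the pools are not covered, since each strain and tissue had 1 pool. An effect of dye or spot that repeats on every array of a tissue is not covered either, since no dye swaps were made. The real count for brain was 2710, against a highest of 0 among the other sign patterns of its arrays, and 7682 against 6 for kidney and 4619 against 2 for liver. In each case 1 of 32 patterns, the real one, gave as many. For the differences the real counts of 4193, 1465, 3266 and 5253 stood against a highest of 654, 250, 533 and 8 among 100 splits, and 1 split, the real one, gave as many.

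Many features had ratios of the same direction in all 3 tissues (569). Dim or saturated spots are argued against as the whole source, since 180 of 9929 brighter, unsaturated features also did so, 60 higher and 120 lower, where 33.9 would be shared by independent lists. The other spots of a gene had the same sign for 33 of 60 genes (55.0%, exact 95% interval 41.6 to 67.9, exact binomial p = 0.519). This was 14 of 20 genes with a higher spot and 19 of 40 with a lower one. No clear departure from an even split is what a spot that measures only itself would give. Wrong gene names, which affect part of the spots, could give it too. A dye effect constant for a spot cannot be told apart from strain without dye swaps. Neighbouring genes of different families shared a direction in 4 pairs, against a mean of 5.34 and an upper limit of 10 (95% range) in shuffled orders, so the data do not show the clusters that strain haplotypes could give, and a biological difference between the strains stays open.

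Ribosomal protein genes passed the set test as higher in DBA/2J in brain and liver, with 32 and 33 of 62 genes not past the threshold. With an estimated correlation they did not pass (adjusted p = 0.589 and 0.609). The brain median of 0.36 lay at percentile 100 of 10000 random lists matched on intensity (upper limit of their 95% range 0.042). Loess had already removed the trend with intensity, so this alone could hardly show an effect of spot brightness. Genes of random lists need not vary together as ribosomal ones do (estimated correlation 0.604 in brain), so percentiles overstate how unusual the medians are. A single array is argued against, since the median stayed at 0.28 or more with any 1 brain array left out, although array 1 had a median of -0.10. Without loess the ratios of bright spots were raised as a whole. The brain median of 0.55 then lay at percentile 100 of lists matched on intensity (median 0.18, upper limit 0.23). This argues against spot brightness as the whole source and against the loess step as the source in brain. In kidney the median of 0.66 without loess lay below the matched lists (lower limit 0.68). A dye effect constant for a spot would be the same in every tissue. The excess of the array medians over matched lists was 0.35 in brain and -0.10 in kidney (exact permutation p = 0.0108), and 0.38 and -0.10 without loess (exact permutation p = 0.00866), which argues against such an effect as the whole source. Kidney and liver differed by -0.30 with and without loess (exact permutation p = 0.00216), and brain and liver by 0.16 (exact permutation p = 0.216), or 0.18 without loess (exact permutation p = 0.184). Without matching, the array medians of kidney and liver differed by -0.28, but by 0.43 without loess (exact permutation p = 0.00216 for both), those of brain and kidney by 0.44 and -0.12 (exact permutation p = 0.00866 and 0.139), and those of brain and liver by 0.16 and 0.30 (exact permutation p = 0.186 and 0.0108). A biological difference between the RNA pools may also be the source and was not tested.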

How the results depend on the processing

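The values as deposited, loess over the whole array, the intensity of each array itself or without the restored factor, and the features left out as dim or saturated were chosen as alternatives after the data were seen. A common scale, a robust prior, array weights and a single fit of all arrays kept every count of features per tissue within 1.5 times. Of 211 named values all 211 kept direction and side of the threshold with a common scale, 188 without loess, 205 with each spot on its own, 200 without the restored factor, 201 with whole-array loess and 208 with the intensity of each array itself. The cause was not tested except where given. No value was missing, so asking for at least 2 or for all 6 arrays changed nothing and was not run. Signal over background is not known here.

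With each array's median set to 0 and no loess, brain had 823 features at 1.5-fold, kidney 13113 (5748 at 1.5-fold), all 3 tissues in a single direction 1512, brain and kidney 7113, brain and liver 830, kidney and liver 9288 and the 3 tissues 9421. The correlations were 0.610 for brain and kidney and 0.548 for brain and liver, and 11 kidney lists passed, 9 up and 2 down. Reversed in kidney were Umod (0.11), Scnn1a (0.15), Rpl27a (0.39), Rpl9 (0.61), Rps6 (0.53) and Gpnmb (0.19), and with each spot on its own Gabra2 (0.062). With an estimated correlation 0 lists passed in brain, 0 in kidney and 0 in liver, against 3, 1 and 3 at an unadjusted p below 0.05 in limma's camera. With each tissue as 1 value, the count of 0 in limma (3736 at an unadjusted p below 0.05) became 32 with a common scale, 12 with each spot on its own, 506 with whole-array loess, 45 with the intensity of each array itself, 5 without the restored factor and 18 without saturated features.

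As deposited, with the array medians left below 0, which is a shift of all ratios, 19609 features passed in brain (18721 at 1.5-fold), 11739 in kidney (9123) and 20064 in liver (19792). This alternative was limited to these counts after it was seen. Whole-array loess gave 868 features for brain and liver and correlations of 0.393, 0.535 and 0.457. Without the restored factor kidney had 1364 features at 1.5-fold, brain and liver 773, brain and kidney a correlation of 0.429, and brain 3 lists. Among features past 1.5-fold and the threshold in at least 1 tissue the correlation of brain and kidney was 0.442. Without the dimmer part of the features, where fewer were tested, brain had 1399 (193 at 1.5-fold), kidney 3496 (375), liver 2785, all 3 tissues 179, brain and kidney 2761, the correlations with kidney 0.179 for brain and 0.240 for liver, kidney lists 1 and known alleles 7.

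Leaving out each array in turn gave 1244 (without brain array 4) to 3272 features in brain, with 1571, 1348 and 1379 without arrays 2, 5 and 6, and 266 to 463 at 1.5-fold, 6158 to 7342 in kidney (726 to 860) and 2895 (without liver array 3) to 4555 in liver (454 to 564). All 3 tissues gave 328 and 363 without brain arrays 4 and 5, and up to 596. With each tissue as 1 value there were 0 to 41, with 13 and 19 without brain arrays 2 and 5, 26 without kidney array 5, and 41, 5, 21, 33, 23 and 13 without liver arrays 1 to 6. Differences ranged over 3124 to 4613 for brain and kidney, 1127 to 1533 for brain and liver, 2592 to 3286 for kidney and liver and 4243 to 5672 for the 3 tissues. Correlations ranged over 0.271 to 0.339, 0.411 to 0.455 and 0.346 to 0.397, lists over 4 to 6 in brain, 2 to 3 in kidney and 5 to 6 in liver, and known alleles over 12 to 13. Of 201 named values past the threshold 15 lost it without some array.

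The replicate numbers do not pair the arrays. Deviations of same-numbered arrays correlated between -0.229 and 0.161, above 0.1 in 2 of 18 pairs, and best with their own number in 5 of 18. With the replicate block as a fixed effect 3889, 1318, 3012 and 4867 features differed between brain and kidney, brain and liver, kidney and liver and over the 3 tissues, and with a random replicate block 4023, 1378, 3123 and 5060.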

Other observations

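Both tests of the clock genes, and the choice of the lists described first, were made after the results were seen; none of these lists passed the set test in the tissue named. Enzymes of drug and xenobiotic metabolism differed in both directions in liver, with 14 higher, 20 lower and 25 not past the threshold of 59 (37 past it adjusted over the list alone, median -0.02, adjusted p = 0.474, and adjusted p = 0.805 with an estimated correlation). Aox3 (-1.51 ± 0.34), Cyp3a13 (-1.22 ± 0.43) and the fatty acid hydroxylase Cyp4a10 (-1.02 ± 0.22) were lower and the flavin monooxygenase Fmo2 (1.14 ± 0.33, spots at 1.46 and 0.83) was higher. In kidney the same list gave 10 higher, 15 lower and 34 not past (25 over the list alone, adjusted p = 0.853), with a median of -0.01 and a downward test but a mean of 0.05, led by Aldh1a1, Cyp4a12a, Cyp2a4 and Cyp2a5. Genes of glucose metabolism in liver gave 3 higher, 13 lower and 22 not past of 38 (16 over the list alone, median -0.05, adjusted p = 0.0963, and adjusted p = 0.580 with an estimated correlation), among them Pdha1 (-0.77 ± 0.40), Tpi1 (-0.73 ± 0.28), Pfkl (-0.72 ± 0.23) and G6pc, glucose-6-phosphatase (-0.73 ± 0.30). Genes of sterol and bile acid metabolism in liver gave 11 higher, 8 lower and 19 not past of 38 (20 over the list alone, adjusted p = 0.602), with a median of 0.07 that was -0.01 with whole-array loess. The cholesterol synthesis genes Msmo1 (1.28 ± 0.46) and Fdps (0.88 ± 0.18) were higher, and the bile acid genes Cyp39a1 (-0.83 ± 0.25) and Baat (-0.73 ± 0.11) lower. Tpi1 (-0.54 and -0.82) and Cyp39a1 (-0.50 and -0.51) were lower past the threshold in brain and kidney too. The other genes named from these 2 lists did not pass in all tissues in a single direction. For Tpi1 and Cyp39a1 a dye effect constant for a spot is not separated from strain.

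Genes of proteins secreted by the liver gave 12 higher, 17 lower and 34 not past of 63 in kidney (29 over the list alone, adjusted p = 0.478), with a median of -0.04 that was 0.02 with the intensity left unrestored. The alpha-1-antitrypsin genes Serpina1a (-1.72 ± 0.34), Serpina1b (-1.66 ± 0.14), Serpina1e (-1.55 ± 0.25) and Serpina1d (-1.48 ± 0.53) were lower there. These genes are close paralogs, and which of them each spot measured is not known here. Of 7 sex-linked genes 1 was higher and 2 lower in liver, Eif2s3y (0.36 ± 0.26), Xist (-0.64 ± 0.24) and Usp9y (-0.35 ± 0.14), with 1 higher and 1 lower in brain and 1 higher and 2 lower in kidney, and the set test gave adjusted p = 0.717 in brain, 0.621 in kidney and 0.860 in liver.

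Circadian clock genes gave 10 higher, 2 lower and 7 not past of 19 in kidney (12 over the list alone, median 0.18, adjusted p = 0.1251, and adjusted p = 0.545 with an estimated correlation), with Nr1d1 at 0.67 ± 0.23, Dbp at 0.66 ± 0.31, Usp2 at 0.63 ± 0.29 and Per3 at 0.53 ± 0.30, the last 2 of them not past the threshold without loess. In liver 5 were higher, 3 lower and 11 not past (8 over the list alone, adjusted p = 0.683), with a median of -0.01 but a mean of 0.07 and an upward test, with Dbp at 0.99 ± 0.45, Per3 at 0.48 ± 0.20 and Clock at 0.35 ± 0.11. Wee1 stood at -0.35 ± 0.28 in liver, a call that ended without liver array 1, 3, 4 or 6 (-0.30, -0.33, -0.34 and -0.31).

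A hypothesis drawn from these values is that the kidney pools may have been taken at different phases of the clock. The 9 genes that peak with Dbp averaged 0.38 and the 5 that peak with Arntl -0.10 in kidney, a difference of 0.48 (two-sided exact permutation p = 0.00599, adjusted p = 0.0240 over 4 tests), and without loess it was 0.81 (exact permutation p = 0.0260). Clock, 1 of those 5, went the other way in kidney (0.33 ± 0.18, adjusted p = 0.00332), and 2 of the 5 passed as lower. These genes are regulated together and were measured in 1 pair of pools, so the permutation does not exclude chance. The difference had the same sign in brain (0.18, exact permutation p = 0.127) and liver (0.29, exact permutation p = 0.166), and without loess it was 0.37 in brain (exact permutation p = 0.0325) and 0.44 in liver (exact permutation p = 0.0929). A dye effect constant for a spot, which would act alike in every tissue, stays open, since the kidney difference exceeded that of brain by 0.30 with an exact permutation p of 0.0365 and an adjusted p of 0.0729. The time of tissue collection is not given in the sources used here, and a difference in clock gene expression between the strains cannot be told apart from a difference in collection time.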
